A study of Mus musculus with 10 samples.

How the data were processed

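Total RNA of 10 mouse mesenchymal stem cell cultures was measured on single-colour (Cy3) Agilent arrays, 1 per culture, in 5 groups of 2: wild-type ASC, wild-type BM-MSC, primed Rb/p53-null ASC, primed Rb/p53-null BM-MSC and the tumor line. Per the labels, duplicates are independent cultures collected in exponential growth. The deposited scanner files hold spot signals as intensity, which the authors made with Feature Extraction 10.7.3.1 per the file headers, with background subtracted and dim spots set to surrogate values, and flags per spot. Probe coordinates refer to mm9. The deposited series matrix holds normalized values that read as log2, with medians of 5.04 to 5.06 in all arrays. The authors name limma in their processing notes, and its role, its version and the normalization are not given in the sources used here.

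The main values were computed from the scanner files. For each array, spots marked as outliers were left out, the processed signals of a probe were averaged on the log2 scale, and the array's 75th percentile was subtracted. Of 55681 probes, 37 with no usable spot on some array were dropped. Probes were named from RefSeq symbols by accession (27235), by symbol (3581), by synonym (565) or by symbol in another case (41), and 24259 kept the name in the file, which gave 34734 distinct names. The probe with the highest mean stood for a gene, and the 22596 genes whose probe was well above background on both arrays of at least 1 group were tested. The series matrix correlated with its own scanner column at r = 0.989 to 0.993 across probes, with a slope of 0.981 to 1.01, and was used only as an alternative.

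All 5 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 5 residual and 1.35 prior degrees of freedom, and 7 contrasts were taken. They were null against wild-type cells in each tissue, the difference of these 2 effects, BM-MSC against ASC in null and in wild-type cells, and the tumor line against null and against wild-type BM-MSC. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested in a contrast, with a threshold of 0.05. The median SE of a change was 0.0946 (log2), and 0.134 for the difference of effects. The p-values measure the spread between duplicate cultures alone, and the number of arrays limits the precision. The 8 arrays other than the tumor line shared a slide, with wild-type and null cultures in different lines of positions, and the 2 tumor line arrays shared another.

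Fixed before the data were examined were the groups, contrasts, tests, alternatives, 26 gene lists and the rule for named genes. The lists are the targeted genes (2 members, so no set test), E2F targets and DNA replication, mitosis, p53 targets, CDK inhibitors and D cyclins, osteogenic, adipogenic, chondrogenic, smooth muscle, MSC surface and niche, extracellular matrix, Wnt pathway, BMP and TGF-beta pathway, hypoxia and glycolysis, interferon response, inflammatory cytokines, Hox genes, limb and positional factors, imprinted growth genes, epithelial-mesenchymal regulators, macrophage and myeloid markers, endothelial markers, lymphoid and erythroid markers, skeletal muscle markers, neural and Schwann markers, and sex-linked genes. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists with at least 3 measured members, and again with an estimated correlation and with fry, which asks whether a set moves on balance in one direction and does not compare it with other genes. With the preset correlation 9, 5, 8, 8, 10, 8 and 9 lists were called in the 7 contrasts in the order above. With an estimated correlation only the osteogenic list held, in null and in wild-type BM-MSC against ASC. The 2 settings of camera differ in more than the correlation. In null BM-MSC against ASC the osteogenic estimate was 0.00949, near the preset value, yet unadjusted camera p went from 9.70e-10 to 0.00165. The chondrogenic estimate was -0.0218, and its p went from 0.000934 to 0.0164. A call lost with an estimated correlation therefore does not by itself show that members moved together. The fry test called 17, 22, 16, 22, 23, 24 and 22.

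Named genes were Rb1 and Trp53 in every group. In each contrast they were the 5 largest and 5 smallest changes among genes past the threshold with both arrays of a group above both of the other and the probe used well above background on at least 1 array of each group, leaving out names that are only accessions, clones or models. Also named were up to 3 genes per direction well above background in 1 group and not in the other, ranked by their bound. A change between 2 groups is given only as a bound where the probe used was well above background on no array of 1 of them. Where 1 array of 2 was dim the change is given as measured, and its size then depends on how dim signals are read. From each list came up to 4 changed members, or 2 where none changed, and members against the direction of their list. A few genes that the rule named in 1 contrast (among them Cdkn2a, Cdkn2b, Xist and Ddx3y) are also given in others where the rule did not name them, chosen after their values were seen. A few results that the rule named are not reported here.

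Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, no filter on dim probes, only genes well above background on all 10 arrays, the mean of a gene's probes, replicate numbers as a block, limma with trend and robust variance, the series matrix, the first slide alone, the compared groups alone, a threshold of at least 2-fold, leaving out each array, and the estimated-correlation and fry tests. Crossed replicate numbers and leaving out chromosomes X and Y were added after the data were seen. The procedure was tested on simulated data of 22596 genes with 200 changed. Each simulated gene had 1 spread, pooled over the 5 groups, in all runs. The changes were placed in null BM-MSC, null ASC or the tumor line, tested against wild-type BM-MSC, wild-type ASC and null BM-MSC. Of changes of 1 (log2) the procedure recovered 65.0%, 73.5% and 63.5% in that order. Of changes of 2 it recovered 84.0%, 85.5% and 84.0%, and false calls were 2.29% to 5.77% of the calls. The shifted list was found each time and 0 other lists were called. Simulated genes varied independently, while the estimated correlation in the data was 0.598 in the mitosis list. The simulation therefore does not test how list calls hold when members move together. Primed cultures without gene loss and unprimed null cultures were not analysed here.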

Results

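Gene expression was measured on 10 single-colour oligonucleotide arrays of cultured mouse mesenchymal stem cells, in 5 groups of 2 independent cultures each. The cells came from bone marrow (BM-MSC) or from fat (ASC, adipose-derived) of FVB mice. In 2 groups the cells were wild type. In 2 others they were labelled as lacking Rb1 and Trp53, which encode the retinoblastoma protein and p53. By the culture protocol these cells carried alleles flanked by recombination sites, spent 10 days in osteogenic medium, and then received an adenovirus expressing Cre, the recombinase that removes the flanked DNA. Their source labels name double-null mice instead, and which of the 2 holds is not given in the sources used here. The last group was a line grown from a tumor that formed when primed null BM-MSC were placed under the skin of immunodeficient mice. Part of its labels speak of the tumor and part of a cell line, and it is called the tumor line here. Null BM-MSC and the tumor line were labelled tumorigenic, and null ASC and both wild-type groups non-tumorigenic. The series asked whether the differentiation stage of the cell that loses both genes shapes the sarcoma that follows.

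On each array 53.3% to 58.4% of the spots were well above background, the 75th percentile of the signal was 483 to 621 scanner units, and no spot was saturated. Each level below is a log2 signal over that percentile, as the mean ± SD of 2 arrays, and each change is a log2 difference ± SE from limma. Duplicate cultures correlated with r = 0.994 to 0.996 across genes, which are not independent replicates, and the SD of their differences was 0.338 to 0.411 (log2). Wild-type and null cells of the same tissue were the closest groups, with r = 0.983 between the 2 ASC groups and 0.982 between the 2 BM-MSC groups. The values were 0.937 between wild-type BM-MSC and wild-type ASC and 0.909 to 0.924 between the tumor line and the rest. The first principal component held 45.5% of the variance and parted ASC from the other arrays. The second held 37.2% and parted the tumor line, and the third held 8.24% and parted wild-type from null cultures. On the third the tumor line arrays (4.03 and 2.99) lay between the wild-type and the null cultures. In all 640 results that passed among the genes named for comparisons of 2 groups, both arrays of the higher group lay above both of the lower one, which the naming rule asks of the largest changes.

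The genes to be removed were read first in every group. Rb1 signal was 1.31 (SD under 0.01) in wild-type ASC, 1.91 ± 0.01 in wild-type BM-MSC, -1.94 ± 0.04 in null ASC, 0.60 ± 0.08 in null BM-MSC and -1.97 ± 0.01 in the tumor line. Trp53 signal was 1.06 ± 0.07, 0.77 ± 0.08, -4.81 ± 0.45, -1.0 ± 0.16 and -7.58 ± 0.02 in the same order, and in the tumor line it was not well above background. Against wild-type cells, Rb1 changed by -1.31 ± 0.05 in BM-MSC (adjusted p = 1.41e-05) and -3.25 ± 0.05 in ASC (adjusted p = 1.71e-06), and Trp53 by -1.77 ± 0.20 (adjusted p = 0.000715) and -5.87 ± 0.20 (adjusted p = 8.70e-06). Null BM-MSC thus kept 40.2% of the wild-type Rb1 signal and 29.3% of the Trp53 signal, and null ASC kept 10.5% and 1.71%. The Rb1 probe lies on chromosome 14, 73595408 to 73595467, and the Trp53 probe on chromosome 11, 69404204 to 69404263 (mm9). Where either lies relative to the flanked part of its gene is not determined here, so the levels alone do not measure how much of the DNA was removed, or whether it was removed in culture.

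**Figure D1:**
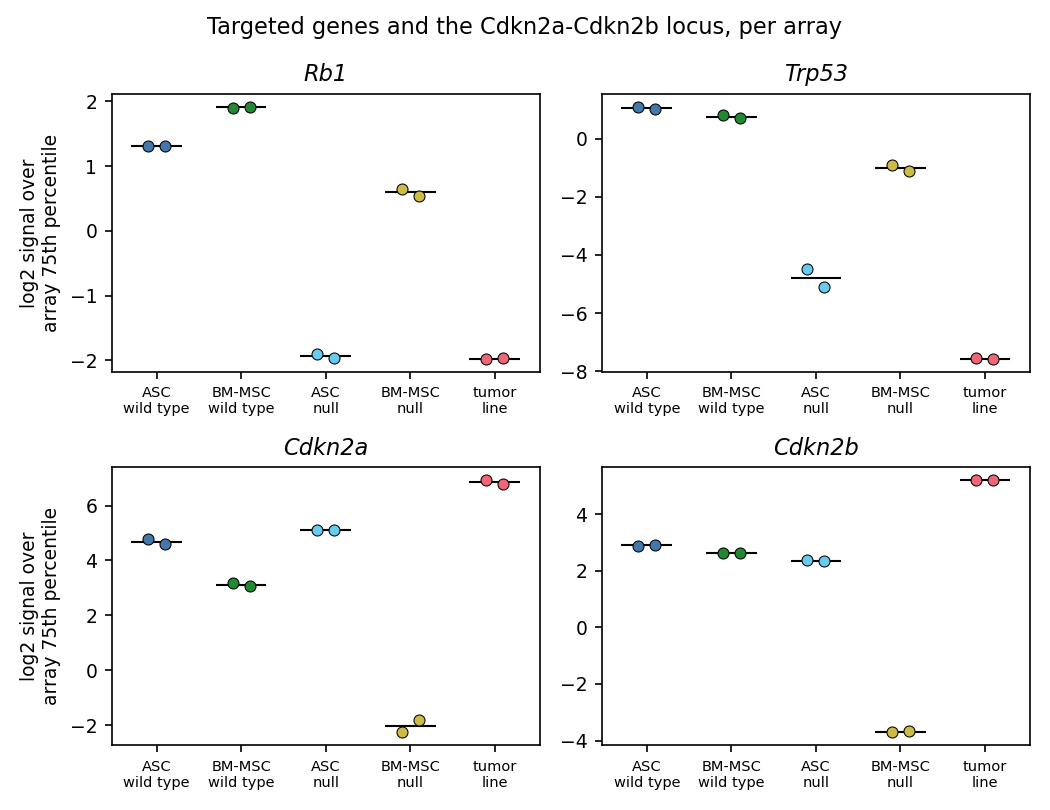
Level of Rb1, Trp53, Cdkn2a and Cdkn2b on each array (y axis, log2 signal over the 75th percentile of the array) in the 5 groups (x axis); points are arrays and horizontal lines the mean of 2. Trp53 averaged -1.0 in null BM-MSC and -4.81 in null ASC, and Cdkn2b averaged -3.70 in null BM-MSC and 5.21 in the tumor line.

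The comparison of primed null with wild-type BM-MSC asked what differed in primed marrow cells labelled as lacking both genes and as tumorigenic. Lumican (Lum), a proteoglycan of collagen fibrils, rose by 7.92 ± 0.13 (adjusted p = 2.37e-06, 2 arrays against 2), and the bone inducer Bmp2 by 6.72 ± 0.34. The Bmp2 level was dim in wild-type BM-MSC (-5.12 ± 0.71). The Wnt agonist Rspo1 (5.86 ± 0.40), the neurotrophin receptor Ngfr (5.67 ± 0.18) and the keratin Krt18 (5.38 ± 0.29) rose as well. The cell cycle inhibitor Cdkn2b, on chromosome 4, 88952276 to 88952335, changed by -6.32 ± 0.04 (adjusted p = 2.73e-08) and its neighbour Cdkn2a, on chromosome 4, 88920405 to 88920464, by -5.16 ± 0.15 (adjusted p = 6.38e-06), on both probes of each gene. The chemokine Cxcl5 (-7.07 ± 0.28), the complement protein C3 (-6.65 ± 0.10), the vesicle protein Svop (-6.88 ± 0.44) and Xist, the RNA of the inactive X chromosome (-6.50 ± 0.19), were among the largest falls. In all, 8920 of 22596 genes passed (4354 higher, 4566 lower), 1848 of them by at least 2-fold.

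Some genes were well above background on both arrays of one BM-MSC group and on none of the other, which allows only a lower bound of the fold. The bound is the bright group's mean over the dim group's mean, with each dim array taken at the higher of its own signal and the lowest signal well above background on that array. The guanylate-binding proteins Gbp8 and Gbp11, interferon-induced GTPases, were at least 50.8-fold and at least 46.7-fold higher in null BM-MSC, and Defa38, a defensin, at least 17.7-fold. The acute-phase protein Saa3 and Etnk2, an ethanolamine kinase, were each at least 25.1-fold lower, and Nlrp2, of the inflammasome sensor family, at least 20.5-fold.

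Cell cycle genes rose together in null BM-MSC and p53 targets fell. Of 38 measured E2F targets and DNA replication genes, 31 rose, 1 fell and 6 did not pass (33 and 1 adjusted over the list alone), with adjusted p = 9.03e-13 for the set and adjusted p = 0.212 with an estimated correlation. Rises included E2f8 (1.11 ± 0.07), the licensing factor Cdt1 (0.92 ± 0.05) and the helicase subunit Mcm6 (0.92 ± 0.06), while Rrm1, a subunit of ribonucleotide reductase, went down (-0.31 ± 0.05). Of 29 mitosis genes, 22 rose, 0 fell and 7 did not pass (25 and 0 adjusted over the list alone), with adjusted p = 5.56e-08 for the set and adjusted p = 0.455 with an estimated correlation. On array 2 of wild-type BM-MSC 27 of them were lower than on array 1 (median -0.15), beside a list median of 0.38. Top2a (0.83 ± 0.11) and the spindle checkpoint kinase Ttk (0.69 ± 0.10) are examples. Of 27 p53 targets, 3 rose, 22 fell and 2 did not pass (3 and 22 adjusted over the list alone), with adjusted p = 1.73e-09 for the set and adjusted p = 0.212 with an estimated correlation. The death-promoting Pmaip1 (-2.65 ± 0.09) and Fas (-2.15 ± 0.06) and the antiproliferative Btg2 (-1.99 ± 0.09) fell, and Gadd45a (1.48 ± 0.07), Plk2 (0.56 ± 0.10) and Sesn1 (0.50 ± 0.06) rose against the list.

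Among differentiation and matrix lists, 31 osteogenic genes gave 12 higher, 5 lower and 14 not past the threshold (13 and 5 adjusted over the list alone), with adjusted p = 0.0315 and adjusted p = 0.212 with an estimated correlation. Osteocalcin (Bglap, 3.61 ± 0.12) and bone sialoprotein (Ibsp, 3.32 ± 0.50) rose, and so did Bglap2 (3.40 ± 0.14), whose sequence is close to that of Bglap, so the 2 signals are not independent. Msx2 (-2.96), Vdr (-2.23), Enpp1 (-0.96), Bmp4 (-0.76) and Tnfrsf11b (-0.56) fell. Of 14 smooth muscle genes, 7 rose, 1 fell and 6 did not pass (7 and 1 adjusted over the list alone), with adjusted p = 0.0289 for the set and adjusted p = 0.472 with an estimated correlation. The smooth muscle myosin Myh11 (2.26 ± 0.15) and actin Actg2 (1.34 ± 0.08) rose and Synpo2 fell (-0.73 ± 0.06), a call that ended with the mean of its 3 probes. Of 35 matrix genes, 20 rose, 7 fell and 8 did not pass (21 and 7 adjusted over the list alone), with adjusted p = 0.000147 for the set and adjusted p = 0.212 with an estimated correlation. Decorin (Dcn, 3.98 ± 0.07) and the basement membrane collagen Col4a1 (1.93 ± 0.06) rose, while Lox (-1.75), Mmp3 (-1.33), Fbln1 (-1.13) and Timp1 (-0.77) fell, as did Fbln2, Fbln5 and Fbn1. Hypoxia and glycolysis genes numbered 18, of which 1 rose, 16 fell and 1 did not pass (1 and 16 adjusted over the list alone), with adjusted p = 5.56e-08 for the set and adjusted p = 0.212 with an estimated correlation. The vasodilator Adm (-2.53 ± 0.09) and the mitophagy receptor Bnip3 (-1.88 ± 0.07) fell, and Pfkfb4 rose (0.39 ± 0.07).

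The cytokine and interferon lists were called in opposite directions in the same cells. Of 17 cytokines, 1 rose, 12 fell and 4 did not pass (1 and 12 adjusted over the list alone), with adjusted p = 3.69e-05 for the set and adjusted p = 0.212 with an estimated correlation. The neutrophil chemokine Cxcl1 changed by -3.87 ± 0.09, and Ccl5 rose (0.67 ± 0.09). Of 25 interferon response genes, 11 rose, 2 fell and 12 did not pass (14 and 2 adjusted over the list alone), with adjusted p = 0.00331 for the set and adjusted p = 0.596 with an estimated correlation. On array 2 of null BM-MSC 24 of these genes were higher than on array 1 (median 0.36), beside a list median of 0.43. The chemokine Cxcl10 rose (1.64 ± 0.10), and Gbp2 (-0.78) and the peptide transporter Tap1 (-0.54) fell. The other 16 lists were not called (adjusted p = 0.0649 to 0.970). CDK inhibitors and D cyclins gave 4 higher and 5 lower of 11 (4 and 5 adjusted over the list alone). MSC surface and niche genes gave 5 higher and 9 lower of 19 (5 and 9 adjusted over the list alone), and endothelial markers 2 higher and 2 lower of 8 (2 and 2 adjusted over the list alone). The mean and the median had opposite signs in the MSC surface, Hox, limb and sex-linked lists, the test following the median except in the sex-linked list. Beside every list above, Xist moved with the group, from 2.13 ± 0.11 in wild-type to -4.37 ± 0.25 in null BM-MSC, where the Y-linked Ddx3y was 1.65 ± 0.01 and 1.95 ± 0.07. Loss of the genes, the virus, the priming and the line of positions on the slide went together, so the comparison is of all of them at once. The sex of the donors is not given, so a difference between donors cannot be separated from these either. The osteogenic call ended with only genes well above background on all 10 arrays (adjusted p = 0.559), without chromosomes X and Y (0.0514), without null BM-MSC array 1 (0.0632) or wild-type BM-MSC array 2 (0.0738; range over settings 0.00199 to 0.559), and the smooth muscle call with the mean of a gene's probes (0.0798), with no filter (0.0949) and without the same arrays (0.0546 and 0.0738; 0.00340 to 0.0949).

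The same question in fat-derived cells, labelled as lacking both genes and as non-tumorigenic, was asked by comparing primed null with wild-type ASC. The secreted Wnt modulators Sfrp4 (5.27 ± 0.13) and Sfrp2 (5.00 ± 0.21), the leucine-rich repeat protein Lrrc17 (5.39 ± 0.13) and the chemokine Ccl5 (4.95 ± 0.09) rose most among named genes well above background on at least 1 array of each group, each with adjusted p = 1.49e-05 or less, 2 arrays against 2. Vgll2, a transcriptional cofactor, rose by 4.75 ± 0.46. The carboxylesterase Ces2e (-6.44 ± 0.62), Trp53 itself (-5.87 ± 0.20), the nucleotide receptor P2ry6 (-5.70 ± 0.08) and the p53-regulated adhesion protein Perp (-5.18 ± 0.05) were among the largest falls. By bounds, the angiotensin receptor Agtr2 was at least 34.5-fold higher in null ASC, Igfbp5 at least 24.6-fold and Rgs7bp at least 17.4-fold. Svop was at least 57.0-fold lower and the sulfotransferase Sult1a1 at least 21.4-fold. In all, 9379 of 22596 genes passed (4594 higher, 4785 lower), 2057 of them by at least 2-fold.

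In null ASC the cell cycle genes of both lists rose together. Of 38 E2F targets and replication genes, 38 rose, 0 fell and 0 did not pass (38 and 0 adjusted over the list alone), with adjusted p = 4.33e-22 for the set and adjusted p = 0.260 with an estimated correlation. E2f8 stood at 2.05 ± 0.07, the primase subunit Prim1 at 1.72 ± 0.04 and Gins1 at 1.68 ± 0.05. Of 29 mitosis genes, 29 rose, 0 fell and 0 did not pass (29 and 0 adjusted over the list alone), with adjusted p = 1.70e-19 for the set and adjusted p = 0.380 with an estimated correlation. Ttk (1.82 ± 0.10), the kinesin Kif2c (1.74 ± 0.07) and the checkpoint kinase Bub1b (1.69 ± 0.09) are examples. Of 27 p53 targets, 0 rose, 24 fell and 3 did not pass (0 and 24 adjusted over the list alone), with adjusted p = 5.54e-16 for the set and adjusted p = 0.0863 with an estimated correlation. After Perp the largest falls were the cell cycle inhibitor Cdkn1a (-3.97 ± 0.08), Trp53inp1 (-3.11 ± 0.06) and Pmaip1 (-3.05 ± 0.09). Of 18 hypoxia and glycolysis genes, 2 rose, 12 fell and 4 did not pass (2 and 13 adjusted over the list alone), with adjusted p = 0.00265 for the set and adjusted p = 0.528 with an estimated correlation. Ankrd37 was lower (-1.25 ± 0.07) and the glycolytic regulators Pfkfb3 (0.43 ± 0.08) and Pfkfb4 (0.56 ± 0.07) higher. Of 25 interferon genes, 15 rose, 1 fell and 9 did not pass (17 and 1 adjusted over the list alone), with adjusted p = 4.59e-05 for the set and adjusted p = 0.556 with an estimated correlation. Cxcl10 (1.67 ± 0.10) and the immunoproteasome subunit Psmb8 (1.37 ± 0.06) rose, while Ifit2 fell (-0.33 ± 0.10).

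The other 20 lists were not called in ASC (adjusted p = 0.0941 to 0.931). The osteogenic list gave 11 higher and 5 lower of 31 (11 and 5 adjusted over the list alone), with Postn (2.19 ± 0.06) higher. The chondrogenic list gave 5 higher and 2 lower of 16 (5 and 2 adjusted over the list alone), with the cartilage regulator Sox9 (2.57 ± 0.07) higher. The BMP and TGF-beta list gave 7 higher and 6 lower of 28 (7 and 6 adjusted over the list alone), with Tgfbi higher (3.40 ± 0.07) and the antagonist Grem1 lower (-1.48 ± 0.09). Macrophage and myeloid markers gave 2 higher and 6 lower of 20 (2 and 6 adjusted over the list alone). The lysozyme Lyz2 fell by 2.99 and the class II chain H2-Ab1 was at least 3.95-fold lower, while Cd74 rose (1.84 ± 0.26). The endothelial receptor Flt1 fell by 2.81. Cdkn2b changed by -0.54 ± 0.04 and Cdkn2a by 0.42 ± 0.15 (adjusted p = 0.000115 and 0.0679), Ddx3y by -0.95 ± 0.10 and Xist by 0.06 ± 0.19 (adjusted p = 0.000419 and 0.849). Opposite signs of mean and median were found in the CDK inhibitor, MSC surface, BMP, lymphoid and skeletal muscle lists, the test following the mean in all but the first, and in the neural list the test was positive while both were negative. As in BM-MSC, loss, virus, priming and slide position went together.

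The difference between these 2 effects asks directly whether the change from wild-type to primed null cells was the same in marrow and fat cells. Of 22596 genes, 7195 passed (3451 with the higher change in BM-MSC, 3744 with the higher change in ASC), 2232 of them by at least 2-fold. Among named genes well above background on at least 1 array of each of the 4 groups, lumican had the largest positive difference (9.23 ± 0.18, adjusted p = 6.77e-06; up in BM-MSC, -1.32 ± 0.13 in ASC), followed by the formin Fhod3 (6.46 ± 0.24), Klhl30 (5.79 ± 0.25), the interferon-induced Gbp4 (5.46 ± 0.32) and Bglap2 (5.13 ± 0.19). Cxcl5 (-8.47 ± 0.40), Sfrp2 (-8.11 ± 0.29), the cell cycle arrest protein Rprm (-7.08 ± 0.31), Kng1 (-6.70 ± 0.27), whose sequence resembles that of Kng2, and the retinoic acid enzyme Aldh1a2 (-6.57 ± 0.09, adjusted p = 1.61e-06) had the largest negative ones. Rb1 differed by 1.93 ± 0.07 and Trp53 by 4.10 ± 0.28, both having fallen less in BM-MSC.

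Cell cycle genes rose less and p53 targets fell less in BM-MSC than in ASC. By the test of the difference, the E2F list had 0 higher, 32 lower and 6 not passed (0 higher and 35 lower adjusted over the list alone). Their median was -0.64, with adjusted p = 4.10e-13 for the set and adjusted p = 0.330 with an estimated correlation. Mitosis genes had 0 higher, 28 lower and 1 not passed (0 higher and 28 lower adjusted over the list alone). Their median was -1.05, with adjusted p = 1.61e-15 for the set and adjusted p = 0.373 with an estimated correlation. Kif2c (-1.56 ± 0.10) and the mitotic activator Cdc20 (-1.39 ± 0.12) were among them. The p53 targets had 19 higher, 1 lower and 7 not passed (20 higher and 1 lower adjusted over the list alone). Their median was 0.71, with adjusted p = 2.33e-10 for the set and adjusted p = 0.224 with an estimated correlation. Perp (3.36 ± 0.07) and Cdkn1a (2.62 ± 0.12) were positive and Fas (-0.36 ± 0.08) negative. Matrix genes had 22 higher and 7 lower of 35 (22 higher and 8 lower adjusted over the list alone), with adjusted p = 0.000137 and adjusted p = 0.330 with an estimated correlation. The collagen Col8a1 (3.35 ± 0.14) was positive and Col14a1, Col15a1, Fbln1, Fbn1, Lox, Mmp9 and Timp1 were negative (-2.73 to -0.71). Inflammatory cytokines had 2 higher and 9 lower of 17 (2 higher and 9 lower adjusted over the list alone). The cytokine median was -0.71, with adjusted p = 0.000417 and adjusted p = 0.330 with an estimated correlation. Lif (1.30) and Ptgs2 (1.10) went against the list. Col15a1, Lif and the smooth muscle regulator Myocd were not well above background in every group, so their differences depend on how dim signals are read.

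Hypoxia and glycolysis genes had 2 higher and 11 lower of 18 differences (2 higher and 11 lower adjusted over the list alone). The hypoxia median was -0.52, with adjusted p = 0.00566 and adjusted p = 0.474 with an estimated correlation. Ndrg1 (0.70) and P4ha1 (0.82) were positive. Adipogenic genes had 2 higher and 9 lower of 19 (3 higher and 9 lower adjusted over the list alone). The adipogenic median was -0.54, with adjusted p = 0.0491 and adjusted p = 0.474 with an estimated correlation. The lipid carrier Fabp4 was the most negative (-4.80 ± 0.17), and Fasn (0.67) and Lpl (0.54) were positive. Smooth muscle genes had 6 higher and 2 lower of 14 (8 higher and 3 lower adjusted over the list alone). The smooth muscle median was 0.37, with adjusted p = 0.0450 and adjusted p = 0.560 with an estimated correlation. Myh11 (3.62 ± 0.21) was positive, and Myocd (-2.54) and Synpo2 (-0.86) negative. The other 17 lists were not called (adjusted p = 0.152 to 0.962). The osteogenic list had 9 higher and 10 lower of 31 (11 and 10 adjusted over the list alone), with Bglap at 4.43 ± 0.18. CDK inhibitors and D cyclins had 3 higher and 5 lower of 11 (3 and 5 adjusted over the list alone), with Cdkn2b at -5.78 ± 0.06. In the epithelial-mesenchymal, endothelial, lymphoid and sex-linked lists the mean and the median differed in sign, the test following the median. Xist differed by -6.56 ± 0.27 and Ddx3y by 1.25 ± 0.14 beside these lists, so a difference between donors cannot be separated from the differences above.

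Genes called in both tissues shared a direction more often than independent calls would give: 2094 were higher in both (885.2 if independent), 2174 lower in both (966.9) and 1180 opposite (1850.3), with r = 0.279 between the 2 changes across all genes and no array shared. The adipogenic call on the difference ended without null ASC array 2 (adjusted p = 0.108), wild-type ASC array 2 (0.0645) or null BM-MSC array 1 (0.0646), with the 4 groups alone or their slide alone (0.0590), and with genes above background on all 10 arrays (0.141; range 0.00914 to 0.141). The smooth muscle call ended without the same 3 arrays (0.0980, 0.0739 and 0.0711), without wild-type BM-MSC array 2 (0.0917), and with the 4 groups or their slide alone (0.0564; range 0.00620 to 0.0980).

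**Figure D2:**
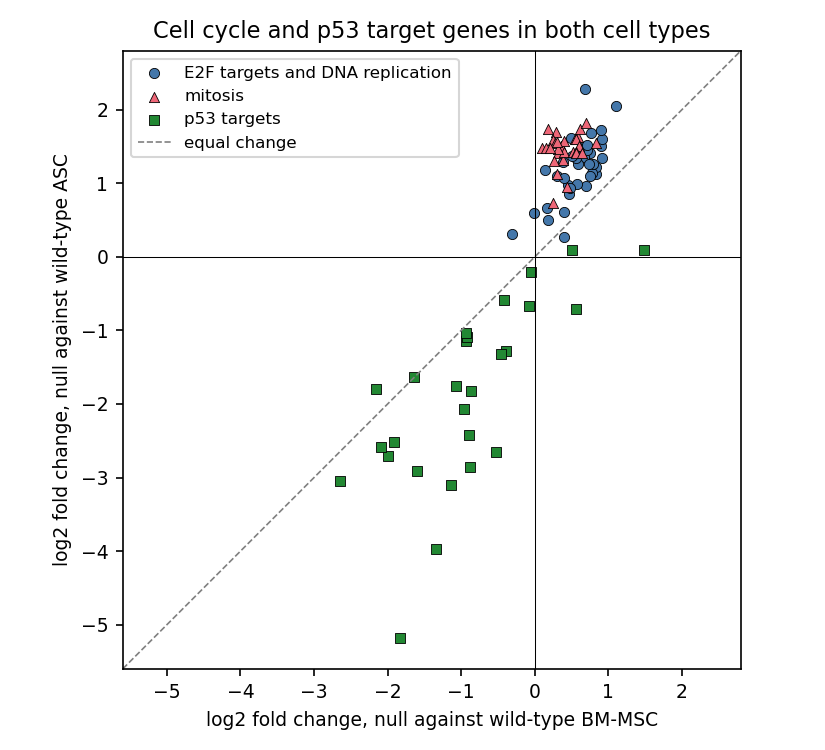
Change in null against wild-type BM-MSC (x axis, log2) against change in null against wild-type ASC (y axis, log2) for each measured gene of the E2F target, mitosis and p53 target lists; each point is a gene and the dashed line marks equal change. The p53 targets had a median of -0.93 in BM-MSC and -1.80 in ASC, and the mitosis genes 0.38 and 1.48.

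Comparing the primed null cells of both tissues set the tumorigenic against the non-tumorigenic mutant culture. Bone sialoprotein (Ibsp) was at least 1826-fold higher in null BM-MSC, the cartilage collagen Col2a1 at least 1134-fold and the developmental cofactor Eya2 at least 1538-fold, and osteocalcin 2 (Bglap2) differed by 9.75 ± 0.14 (adjusted p = 6.23e-08). Eva1c (10.79 ± 0.16), the calcium-binding S100b (10.24 ± 0.18), the scavenging chemokine receptor Ackr4 (10.06 ± 0.25) and the citrate transporter Slc13a5 (9.75 ± 0.06) were also higher. Plac8 (-9.54 ± 0.32), the peptide hormone Cck (-9.49 ± 0.28), the Wnt antagonist Frzb (-9.37 ± 0.53) and the retinaldehyde dehydrogenase Aldh1a1 (-9.07 ± 0.23) were lower, as were S100g, Frmd3 and Pdlim3 by bounds (at least 1561-fold, at least 648-fold and at least 405-fold). Frzb was dim in null BM-MSC (-5.46 ± 1.31) and Ackr4 in null ASC (-5.00 ± 0.57), so the sizes of these 2 changes are uncertain. In all, 12524 genes passed (5883 higher, 6641 lower), 4287 of them by at least 2-fold.

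Of 31 osteogenic genes, 23 rose, 2 fell and 6 did not pass (24 and 2 adjusted over the list alone), with adjusted p = 1.21e-08 for the set. This call held, with adjusted p = 0.0412 with an estimated correlation. The transcription factor Dlx5 was at least 58.2-fold higher, and Msx2 (-3.58 ± 0.09) and the osteoclast factor Tnfsf11, not well above background in null BM-MSC, were lower. All 14 smooth muscle genes rose (14 higher and 0 lower adjusted over the list alone; adjusted p = 2.03e-07, and adjusted p = 0.168 with an estimated correlation), Actg2 by 5.09 ± 0.08 and Cnn1 by 3.07 ± 0.10. Of 16 chondrogenic genes, 10 rose, 1 fell and 5 did not pass (10 and 1 adjusted over the list alone), with adjusted p = 0.00389 for the set and adjusted p = 0.168 with an estimated correlation. Comp stood at 7.01 ± 0.41 and Acan at -0.54 ± 0.16. Of 25 Wnt pathway genes, 15 rose, 5 fell and 5 did not pass (16 and 6 adjusted over the list alone), with adjusted p = 0.00396 for the set and adjusted p = 0.168 with an estimated correlation. The receptor Lgr5 and the inhibitor Wif1 were at least 349-fold and at least 76.0-fold higher, and Dkk2 (-8.79 ± 0.36), Lef1 (not well above background in null BM-MSC), Sfrp4 (-2.69), Wnt4 (-2.43) and Wnt5a (-2.18) were lower.

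**Figure D3:**
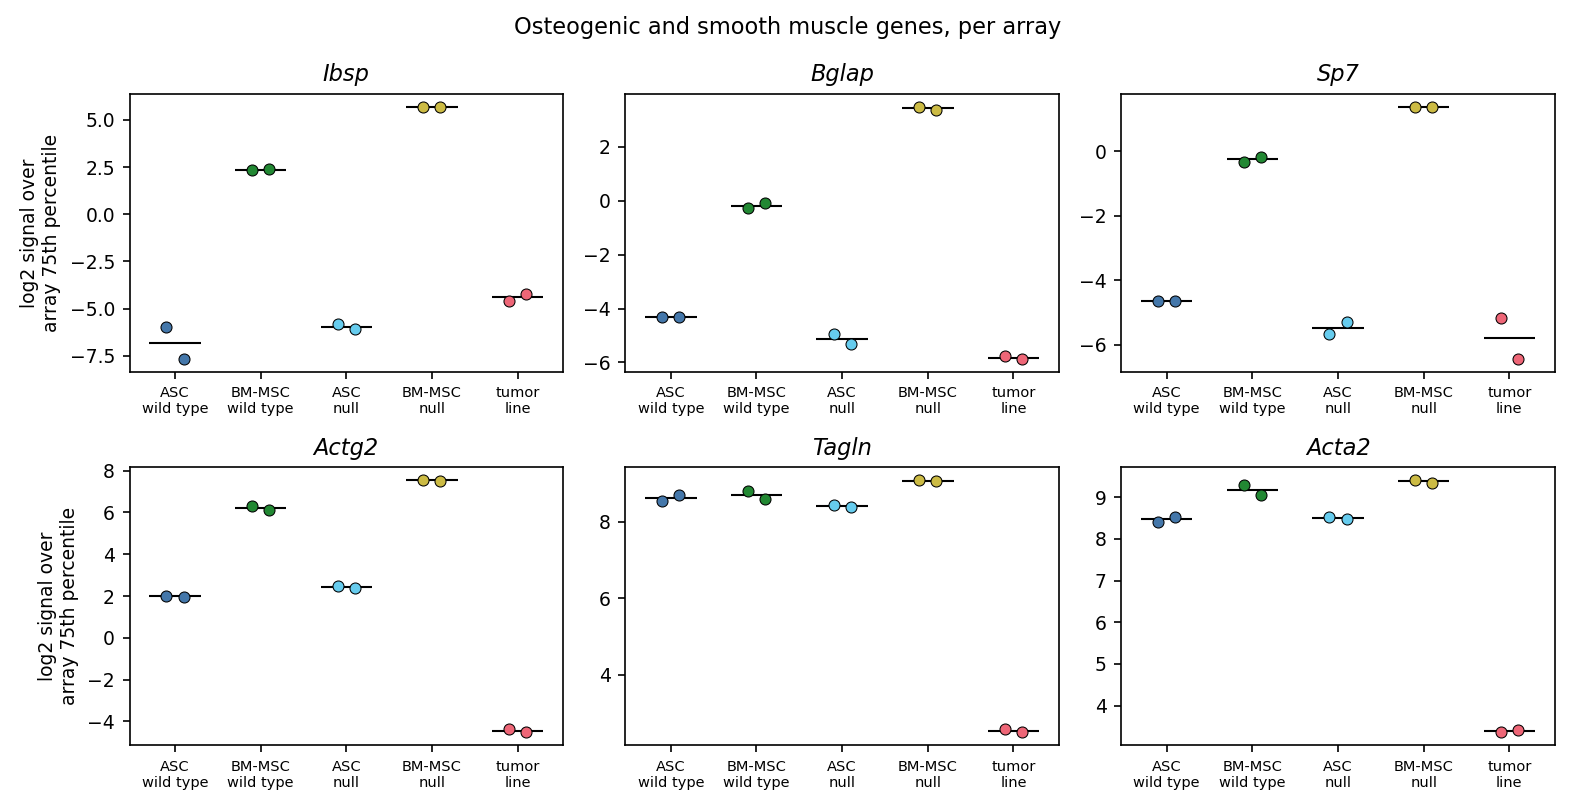
Level of the bone genes Ibsp, Bglap and Sp7 and the contractile genes Actg2, Tagln and Acta2 on each array (y axis, log2 signal over the 75th percentile of the array) in the 5 groups (x axis); points are arrays and horizontal lines the mean of 2. Ibsp averaged 5.69 in null BM-MSC and -5.96 in null ASC, and Acta2 averaged 9.38 in null BM-MSC and 3.39 in the tumor line.

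Interferon response genes were lower in null BM-MSC than in null ASC. Of 25 members, 0 rose, 23 fell and 2 did not pass (0 and 23 adjusted over the list alone), with adjusted p = 1.76e-09 for the set and adjusted p = 0.469 with an estimated correlation. The antiviral enzyme Oas1a stood at -5.95 ± 0.22, Cxcl10 at -5.01 ± 0.10 and the regulator Irf7 at -4.69 ± 0.12. Of 38 E2F targets, 4 rose, 27 fell and 7 did not pass (4 and 28 adjusted over the list alone), with adjusted p = 0.000754 for the set and adjusted p = 0.469 with an estimated correlation. The activator E2f2 (-1.48 ± 0.11) and the cyclin Ccne1 (-1.39 ± 0.07) were lower, and E2f1, E2f7, Prim1 and Rrm2 higher. Of 29 mitosis genes, 1 rose, 25 fell and 3 did not pass (1 and 25 adjusted over the list alone), with adjusted p = 3.31e-06 for the set and adjusted p = 0.469 with an estimated correlation. Plk1 stood at -1.13 ± 0.09. Cdca8 went the other way. Of 18 hypoxia genes, 5 rose, 12 fell and 1 did not pass (5 and 12 adjusted over the list alone), with adjusted p = 0.0200 for the set and adjusted p = 0.469 with an estimated correlation. Egln3 was at least 8.91-fold lower. Adm, Car9, Ndrg1, P4ha1 and Pfkfb4 were higher. The remaining 17 lists were not called (adjusted p = 0.0606 to 0.981). The p53 targets gave 15 higher and 9 lower of 27 (16 and 9 adjusted over the list alone), Perp being 3.58 ± 0.05. Imprinted growth genes gave 7 higher and 6 lower of 13 (7 and 6 adjusted over the list alone), with H19 at 8.33 ± 0.09 and Dlk1 at -5.45 ± 0.07. Limb and positional factors gave 6 higher and 7 lower of 15 (6 and 7 adjusted over the list alone), the hindlimb factor Pitx1 being at least 1086-fold higher and Hand2 at least 26.0-fold lower. Rb1 (2.53 ± 0.05) and Trp53 (3.80 ± 0.20) were higher in null BM-MSC, Cdkn2a (-7.15 ± 0.15) and Cdkn2b (-6.06 ± 0.04) lower. Xist (-8.86 ± 0.19) and Ddx3y (3.47 ± 0.10) differed with the group. Mean and median differed in sign for the adipogenic, MSC surface and macrophage lists, the test following the mean.

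The wild-type cultures show how far marrow and fat cells differed without loss of either gene, though they are not labelled as primed. The Wnt modulators Sfrp2 (10.74 ± 0.21) and Rspo2 (9.84 ± 0.25), the collagen Col8a2 (10.13 ± 0.18), Slc13a5 (9.82 ± 0.06, adjusted p = 3.91e-09) and Eva1c (9.42 ± 0.16) were higher in BM-MSC. Cck (-11.17 ± 0.28), the aldehyde dehydrogenases Aldh1a7 (-9.87 ± 0.66) and Aldh1a1 (-9.83 ± 0.23), Plac8 (-9.10 ± 0.32) and the calcium-binding S100g (-8.99 ± 0.71) were higher in ASC. By bounds, Col2a1 was at least 2867-fold, Eya2 at least 1523-fold and the ribosomal paralog Rpl39l at least 1139-fold higher in BM-MSC. The iron transport enzyme Heph was at least 781-fold lower, the acyltransferase Mogat2 at least 579-fold and Frzb at least 560.0-fold. Rb1 differed by 0.60 ± 0.05 and Trp53 by -0.30 ± 0.20 (adjusted p = 0.254). In all, 12209 genes passed (5804 higher, 6405 lower in BM-MSC), 4054 of them by at least 2-fold.

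The bone list already stood apart between wild-type cultures. Of 31 osteogenic genes, 23 rose, 1 fell and 7 did not pass (23 and 1 adjusted over the list alone). Adjusted p was 8.28e-08 for the set, and the call held, with adjusted p = 0.0478 with an estimated correlation. Osteopontin (Spp1) stood at 7.58 ± 0.24, Bmp4 at 7.14 ± 0.10 and Msx2 at -0.90 ± 0.09. Of 16 chondrogenic genes, 10 rose, 2 fell and 4 did not pass (10 and 2 adjusted over the list alone), with adjusted p = 0.00794 for the set and adjusted p = 0.173 with an estimated correlation. Sox9 was higher (4.30 ± 0.07). Acan and Col11a2 were lower. Of 14 smooth muscle genes, 10 rose, 1 fell and 3 did not pass (10 and 1 adjusted over the list alone), with adjusted p = 0.000102 for the set and adjusted p = 0.387 with an estimated correlation. Actg2 was higher (4.20 ± 0.08) and Myh11 lower (-1.78 ± 0.15). Of 25 Wnt genes, 15 rose, 4 fell and 6 did not pass (15 and 4 adjusted over the list alone), with adjusted p = 0.000849 for the set and adjusted p = 0.173 with an estimated correlation. The antagonist Dkk2 was at least 417-fold lower. Fzd2, Fzd7 and Wnt5a were lower too. Interferon genes were lower in BM-MSC here too. Of 25 members, 3 rose, 22 fell and 0 did not pass (3 and 22 adjusted over the list alone), with adjusted p = 7.18e-07 for the set and adjusted p = 0.495 with an estimated correlation. Oas1a stood at -5.54 ± 0.22, and Gbp2 (1.06), Psmb8 (0.50) and Psmb9 (0.79) went against the list. Of 34 Hox genes, which mark body position, 8 rose, 19 fell and 7 did not pass (8 and 20 adjusted over the list alone), with adjusted p = 0.0314 for the set and adjusted p = 0.495 with an estimated correlation. Hoxb7 was at least 296-fold and Hoxa11 at least 278-fold lower, while Hoxa10, Hoxa7, Hoxa9, Hoxc10, Hoxc11, Hoxc5 and Hoxc9 were among those that were higher. Outside that list Pitx1 was at least 1098-fold higher in BM-MSC.

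Cell cycle lists were higher in wild-type BM-MSC than in wild-type ASC, the opposite of the null cultures. Of 38 E2F targets, 20 rose, 5 fell and 13 did not pass (20 and 5 adjusted over the list alone), with adjusted p = 0.0107 for the set and adjusted p = 0.614 with an estimated correlation. Prim1 stood at 1.03 ± 0.04 and Ccne1 at -1.07 ± 0.07. Cdt1, Chaf1b, E2f2 and Mcm5 were lower as well. Of 29 mitosis genes, 22 rose, 1 fell and 6 did not pass (22 and 1 adjusted over the list alone), with adjusted p = 2.13e-05 for the set and adjusted p = 0.564 with an estimated correlation. Birc5 stood at 0.92 ± 0.07. Plk1 was lower. Duplicates differed in these 2 lists as well, beside list medians of 0.25 and 0.46. On array 2 of wild-type ASC 30 E2F targets and 25 mitosis genes were higher than on array 1 (medians 0.085 and 0.117). On array 2 of wild-type BM-MSC 32 and 27 were lower than on array 1 (medians -0.089 and -0.15). Of 27 p53 targets, 6 rose, 16 fell and 5 did not pass (6 and 18 adjusted over the list alone), with adjusted p = 0.0163 for the set and adjusted p = 0.495 with an estimated correlation. The stress gene Gadd45a stood at -2.40 ± 0.07. Ddit4, Perp, Phlda3, Plk2, Polk and Sesn1 were higher. Of 18 hypoxia genes, 4 rose, 13 fell and 1 did not pass (4 and 13 adjusted over the list alone), with adjusted p = 0.0451 for the set and adjusted p = 0.564 with an estimated correlation. Ankrd37 (-2.32 ± 0.07) was lower, and Adm (2.43 ± 0.09), Car9, Ndrg1 and Pfkfb4 higher. The other 15 lists were not called (adjusted p = 0.127 to 0.967). Adipogenic genes gave 10 higher and 7 lower of 19 (10 and 7 adjusted over the list alone), the master regulator Pparg being higher (4.32 ± 0.07) and Lpl lower (-5.29 ± 0.06). Skeletal muscle markers gave 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone), and neural and Schwann markers 3 higher and 2 lower of 8 (3 and 2 adjusted over the list alone). Xist (-2.30 ± 0.19) and Ddx3y (2.22 ± 0.10) differed between the tissues. Mean and median differed in sign for the limb, imprinted, epithelial-mesenchymal and neural lists, the test following the mean in the limb and neural lists. The hypoxia call ended with median centring (adjusted p = 0.0549), genes above background on all 10 arrays (0.102), the 2 groups alone (0.0657), the slide alone (0.0505), crossed replicate numbers as a block (0.0893), and without wild-type ASC array 2 (0.0723) or wild-type BM-MSC array 2 (0.0550; range 0.0168 to 0.102). With genes above background on all 10 arrays the chondrogenic call ended (0.403; range 0.00393 to 0.403) and the Hox list turned direction (0.943; range 0.00325 to 0.943).

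The tumor line was compared with primed null BM-MSC, the cells it is labelled as derived from, to ask what differed after growth as a tumor. Among named genes well above background on at least 1 array of each group, the largest falls were the smooth muscle actin Actg2 at -11.97 ± 0.08 (adjusted p = 6.74e-09), Ibsp at -10.09 ± 0.50 and Bglap2 at -9.57 ± 0.14, along with S100b (-10.32 ± 0.18) and the prostacyclin synthase Ptgis (-9.96 ± 0.14). Aggrecan (Acan), a cartilage proteoglycan, rose by 9.72 ± 0.16, the imprinted Dlk1 by 9.60 ± 0.07, Cdkn2b by 8.91 ± 0.04, Cdkn2a by 8.89 ± 0.15 and the glutathione transferase Mgst2 by 7.89 ± 0.08. By bounds, the phospholipase Pla2g7 was at least 311-fold higher, the hypoxia-induced Egln3 at least 255-fold and the kinase Rps6ka6 at least 155-fold. Ctla2a was at least 2308-fold, Igfbp5 at least 1895-fold and Ackr4 at least 1492-fold lower. Rb1 changed by -2.57 ± 0.05 and Trp53 was at least 22.3-fold lower. In all, 15714 genes passed (7809 higher, 7905 lower), 6526 of them by at least 2-fold.

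Of 14 smooth muscle genes, 0 rose, 13 fell and 1 did not pass (0 and 13 adjusted over the list alone), with adjusted p = 2.86e-07 for the set and adjusted p = 0.261 with an estimated correlation. Tagln (-6.52 ± 0.09) and Acta2 (-5.99 ± 0.09) are examples. Of 35 matrix genes, 4 rose, 30 fell and 1 did not pass (4 and 30 adjusted over the list alone), with adjusted p = 3.51e-07 for the set and adjusted p = 0.261 with an estimated correlation. The collagenase Mmp13 fell by 8.48, while Mmp9 (6.64 ± 0.20), Dcn (2.53), Lum (2.47) and Fbln2 (0.90) rose. Of 31 osteogenic genes, 8 rose, 19 fell and 4 did not pass (8 and 19 adjusted over the list alone), with adjusted p = 0.0160 for the set and adjusted p = 0.261 with an estimated correlation. The mineralising phosphatase Alpl was at least 186-fold lower. Against the list, Spp1 (3.37), Msx2 (2.65), Enpp1 (2.29), Phex (1.52), Tnfrsf11b (1.47), Ank (1.31) and Bmp2 (1.20) were among those that rose. Of 25 Wnt genes, 6 rose, 16 fell and 3 did not pass (6 and 16 adjusted over the list alone), with adjusted p = 0.0419 for the set and adjusted p = 0.368 with an estimated correlation. The Wnt inhibitor Sfrp1 stood at -6.16 ± 0.09. Dkk2, Dkk3, Lef1, Tcf7, Wnt5a and Wnt5b rose. Of 28 BMP and TGF-beta genes, 5 rose, 18 fell and 5 did not pass (5 and 18 adjusted over the list alone), with adjusted p = 0.0179 for the set and adjusted p = 0.401 with an estimated correlation. The inhibitor Smad6 stood at -4.76 ± 0.08. Bmpr1b, Grem1, Id4, Smad9 and Tgfbi rose.

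Cell cycle and hypoxia genes were higher in the tumor line than in null BM-MSC. Against wild-type BM-MSC the hypoxia list was not called. It had 9 higher and 7 lower of 18, a median of 0.12 and adjusted p = 0.714 for the set. Of 38 E2F targets, 30 rose, 3 fell and 5 did not pass (30 and 3 adjusted over the list alone), with adjusted p = 3.82e-05 for the set and adjusted p = 0.401 with an estimated correlation. Cdt1 stood at 1.37 ± 0.05. Cdc25a, E2f7 and Pcna fell. Of 29 mitosis genes, 26 rose, 1 fell and 2 did not pass (26 and 1 adjusted over the list alone), with adjusted p = 3.36e-06 for the set and adjusted p = 0.444 with an estimated correlation. The centromere motor Cenpe stood at 2.16 ± 0.10 and Top2a at 1.98 ± 0.11. Cdk1 fell. Of 18 hypoxia genes, 13 rose, 4 fell and 1 did not pass (13 and 4 adjusted over the list alone), with adjusted p = 0.0205 for the set and adjusted p = 0.401 with an estimated correlation. Bnip3 stood at 2.27 ± 0.07 and the vessel growth factor Vegfa at 2.05 ± 0.06. Car9, P4ha1, P4ha2 and Pfkfb4 fell. The other 17 lists were not called (adjusted p = 0.0867 to 0.785). Macrophage and myeloid markers gave 12 higher and 5 lower of 20 (12 and 6 adjusted over the list alone), the complement chain C1qa being at least 6.49-fold and the adaptor Tyrobp at least 9.82-fold higher. Lymphoid and erythroid markers gave 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone), the globin Hba-a1 being 3.98 ± 0.24. Hox genes gave 13 higher and 7 lower of 34 (13 and 7 adjusted over the list alone), Hoxb7 being at least 89.8-fold higher. Epithelial-mesenchymal regulators gave 4 higher and 6 lower of 13 (4 and 6 adjusted over the list alone), the adhesion protein Cdh1 being at least 8.18-fold lower. Ddx3y was at least 172-fold lower, Eif2s3y at least 35.2-fold lower and Xist higher (2.88 ± 0.19), beside each of these lists. Mean and median differed in sign for the adipogenic, epithelial-mesenchymal and neural lists, the test following the median in the adipogenic and neural lists. The tumor line alone sat on the other slide, so slide and group cannot be told apart, and with genes above background on all 10 arrays the osteogenic (adjusted p = 0.122; range 0.00154 to 0.122), hypoxia (0.0734; 0.00200 to 0.0734) and Wnt calls (0.122; 0.0150 to 0.122) ended. The Wnt call also ended with the 2 groups alone (0.0636) and without null BM-MSC array 1 (0.0581) or array 2 (0.0508).

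**Figure D4:**
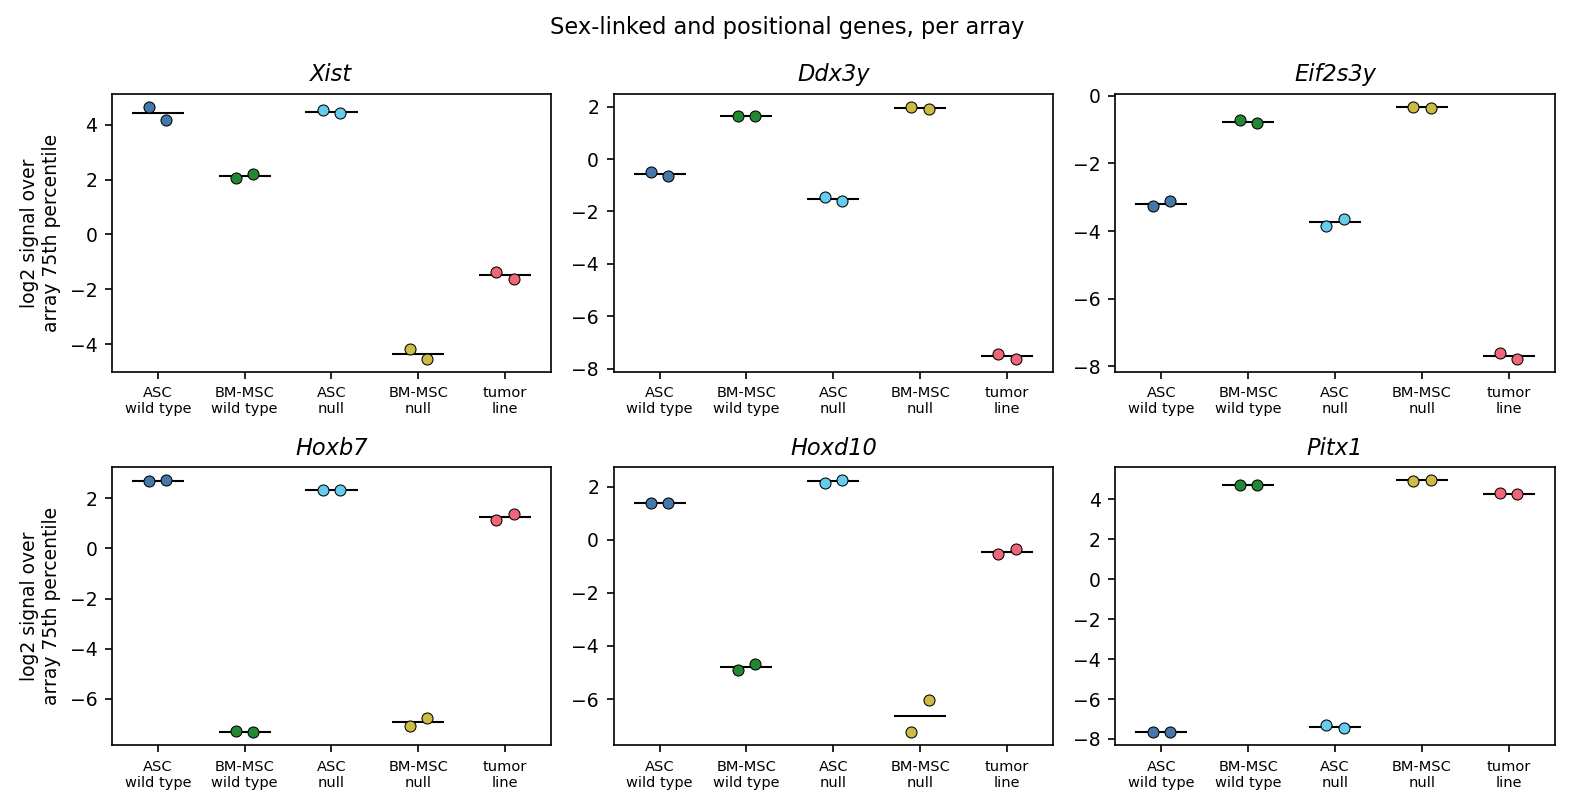
Level of the sex-linked Xist, Ddx3y and Eif2s3y and the positional genes Hoxb7, Hoxd10 and Pitx1 on each array (y axis, log2 signal over the 75th percentile of the array) in the 5 groups (x axis); points are arrays and horizontal lines the mean of 2. In the tumor line Ddx3y averaged -7.53, Hoxb7 1.26 and Pitx1 4.29.

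Against wild-type BM-MSC, the comparison spans everything between the starting tissue and the tumor line. Lumican (10.38 ± 0.13), Acan (10.38 ± 0.16), Rspo1 (9.74 ± 0.40), Bmp2 (7.91 ± 0.34) and the immune cell adaptor Fyb (7.51 ± 0.20) rose most among named genes well above background on at least 1 array of each group. Acan and Bmp2 were dim in wild-type BM-MSC (-5.62 ± 0.33 and -5.12 ± 0.71), so the sizes of their rises are uncertain. Actg2 (-10.63 ± 0.08), the monooxygenase Cyp1b1 (-9.92 ± 0.20), haptoglobin (Hp, -9.85 ± 0.15), the annexin Anxa8 (-9.22 ± 0.07) and the receptor ligand Gas6 (-9.17 ± 0.05, adjusted p = 8.46e-09) fell most among the same genes. By bounds, Pla2g7 was at least 375-fold, Bex2 at least 184-fold and the homeobox factor Lhx8 at least 170.0-fold higher. The paralogs Ctla2a and Ctla2b, which are similar in sequence, were at least 2106-fold and at least 696-fold lower and the small heat shock protein Hspb8 at least 481-fold. Rb1 changed by -3.88 ± 0.05 and Trp53 was at least 76.0-fold lower. In all, 15320 genes passed (7446 higher, 7874 lower), 6362 of them by at least 2-fold.

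Of 38 E2F targets, 34 rose, 1 fell and 3 did not pass (34 and 1 adjusted over the list alone), with adjusted p = 6.78e-10 for the set and adjusted p = 0.242 with an estimated correlation. E2f8 stood at 2.60 ± 0.07. Rrm1 fell. Of 29 mitosis genes, 28 rose, 1 fell and 0 did not pass (28 and 1 adjusted over the list alone), with adjusted p = 4.95e-09 for the set and adjusted p = 0.384 with an estimated correlation. Top2a stood at 2.81 ± 0.11. Cdk1 fell. Of 27 p53 targets, 4 rose, 21 fell and 2 did not pass (4 and 21 adjusted over the list alone), with adjusted p = 4.51e-05 for the set and adjusted p = 0.242 with an estimated correlation. The epoxide hydrolase Ephx1 (-4.28 ± 0.07) and Cdkn1a (-3.14 ± 0.08) fell and Gadd45a (3.14 ± 0.07), Ddit4, Gdf15 and Plk2 rose. All 14 smooth muscle genes fell (0 higher and 14 lower adjusted over the list alone; adjusted p = 1.46e-07, and adjusted p = 0.242 with an estimated correlation), Cnn1 changing by -6.73 ± 0.10. Of 31 osteogenic genes, 7 rose, 18 fell and 6 did not pass (7 and 18 adjusted over the list alone), with adjusted p = 0.0237 for the set and adjusted p = 0.242 with an estimated correlation. Bmp4 (-6.96 ± 0.10) and Ibsp (-6.77 ± 0.50) fell, while Bmp2, Ank, Enpp1, Phex, Spp1 and Tnfrsf11b were among those that rose. Of 35 matrix genes, 6 rose, 26 fell and 3 did not pass (6 and 26 adjusted over the list alone), with adjusted p = 3.61e-05 for the set and adjusted p = 0.242 with an estimated correlation. Dcn (6.51 ± 0.07) and Mmp9 (6.31 ± 0.20) rose with Lum, Col6a3, Fbln2 and Tnc against the list. Of 25 Wnt genes, 6 rose, 14 fell and 5 did not pass (6 and 14 adjusted over the list alone), with adjusted p = 0.0490 for the set and adjusted p = 0.242 with an estimated correlation. Of 28 BMP and TGF-beta genes, 4 rose, 21 fell and 3 did not pass (4 and 21 adjusted over the list alone), with adjusted p = 0.00478 for the set and adjusted p = 0.242 with an estimated correlation. Sfrp1 (-8.88 ± 0.09) and Smad6 (-4.83 ± 0.08) fell. In the Wnt list Dkk2, Dkk3, Lef1, Tcf7, Wnt10b and Wnt5a rose, and in the BMP list Tgfbi (4.63 ± 0.07), Bmpr1b, Inhba and Tgfb1.

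All 4 measured sex-linked genes fell (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.00892, and adjusted p = 0.242 with an estimated correlation). Ddx3y was at least 139.9-fold lower, Eif2s3y at least 26.2-fold and Uty at least 4.54-fold, and Xist changed by -3.62 ± 0.19. The other 16 lists were not called (adjusted p = 0.132 to 0.958). The neural and Schwann markers gave 3 higher and 2 lower of 8 (3 and 2 adjusted over the list alone), with S100b at -8.29 ± 0.18. Interferon response genes gave 9 higher and 9 lower of 25 (9 and 9 adjusted over the list alone), Cxcl10 rising by 4.40. The macrophage list gave 10 higher and 5 lower of 20 (10 and 5 adjusted over the list alone), with Tyrobp at least 11.9-fold higher. Mean and median differed in sign for the epithelial-mesenchymal and neural lists, the test following the median. The osteogenic call ended with genes above background on all 10 arrays (adjusted p = 0.103; range 0.00311 to 0.103). The Wnt call ended with the 2 groups alone (0.106), with replicate numbers as a block (0.0575), without chromosomes X and Y (0.0604), and without wild-type BM-MSC array 1 (0.0501) or array 2 (0.0541; range 0.0214 to 0.106).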

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

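The tests of retained cells, of a lost segment, of a faulty probe, of host cells and of female origin were chosen only after the result was seen; the tests of scaling, of ASC origin and of detection were written down before the value each one measures was seen. The values of the next paragraph and the first pattern were picked out because the change from wild-type to null cells differed between BM-MSC and ASC by the test of the difference itself, and the other 2 patterns because of values in the tumor line.

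By that test 7195 genes differed. The medians of the differences were -0.64 for E2F targets, -1.05 for mitosis, 0.71 for p53 targets, -0.54 for adipogenic, 0.37 for smooth muscle, 0.78 for extracellular matrix, -0.52 for hypoxia and glycolysis and -0.71 for inflammatory cytokine genes. Rb1 differed by 1.93 and Trp53 by 4.10. The largest differences among the named genes were 9.23 for Lum, 6.46 for Fhod3, 5.79 for Klhl30, 5.46 for Gbp4 and 5.13 for Bglap2 on the positive side, and -8.47 for Cxcl5, -8.11 for Sfrp2, -7.08 for Rprm, -6.70 for Kng1 and -6.57 for Aldh1a2 on the negative side.

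The first pattern is that Rb1, Trp53, p53 targets and cell cycle genes all changed less in null BM-MSC than in null ASC. Scaling between arrays is argued against: over quantile normalization, median centring, normexp and the series matrix the lowest median difference of the p53 targets was 0.717 and the highest 0.796. A share of cells that kept both genes in the BM-MSC cultures stays open for the p53 targets. The share solved per gene over 24 targets had a median of 0.259 (bootstrap interval 0.116 to 0.384), against 0.293 of the Trp53 signal kept. The changes of Cdkn2b (-6.32), C3 (-6.65) and Xist (-6.50) leave no room for such a share of cells with wild-type levels of those genes. The share takes it as given that BM-MSC without both genes would change as null ASC did. Between BM-MSC and ASC the p53 targets had a median of -0.44 in wild-type and 0.42 in null cultures. The mitosis genes had 0.46 and -0.69. The near match therefore cannot by itself tell retained cells from wild-type levels that already differed. For 67 cell cycle genes the same share was 0.717 (0.660 to 0.772) against 0.402 of the Rb1 signal kept, inside the allowed factor of 2. Its interval lay above both the Rb1 share and the p53 value. Against 0.359, the Rb1 signal above the tumor line's level, the share was at the very edge of that factor. The interval treats the genes as independent, although the estimated correlation was 0.308 in the E2F list and 0.598 in the mitosis list. Whether part of the cell cycle difference is left over was therefore not settled. A different response of the 2 tissues, incomplete recombination without whole cells, and the position of the probes remain open and untested.

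The second pattern is that Cdkn2a and Cdkn2b were nearly lost in null BM-MSC, yet high in the tumor line labelled as derived from them, which also expressed Hox genes such as Hoxb7 that BM-MSC did not. A faulty probe is argued against, since the smallest fall among 4 probes of the 2 genes was -3.37, counting signals not well above background as bounds. Loss of a chromosomal segment reaching the nearest measured neighbours is argued against, since Mtap changed by -0.332 (95% interval -0.577 to -0.0872) and Zfp352 by 0.78, where loss of 1 of 2 copies gives -1; the bound first written, a change of under 0.5 either way, wrongly counted a rise, and a shorter loss was not tested. Tumor line arrays holding cells of ASC origin could not be decided by Hox genes, the mean distance over 34 of them being 1.91 from ASC and 1.73 from BM-MSC (difference 0.180, interval -0.701 to 1.05), while Pitx1 was 4.29 in the tumor line, 4.70 in wild-type BM-MSC and -7.67 in wild-type ASC. Outgrowth of a minor population of the null BM-MSC cultures, and a change of these genes during tumor growth or on the other slide, stay open and untested.

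The third pattern is that Ddx3y and Eif2s3y were not well above background in the tumor line although BM-MSC expressed them. Poorer detection on its slide is argued against, as 0.211% of 1898 autosomal genes of similar signal were below background on both of its arrays. Cells of the host animals in place of the injected ones are argued against by Trp53, not well above background and with a bound of -6.25 from wild-type BM-MSC, although a small share of host cells is not excluded by it. Cells of female origin with an inactive X are argued against by Xist, which was 2.88 higher than in null BM-MSC but -3.62 from wild-type BM-MSC, a culture that expressed both Xist and Y-linked genes and so need not be of 1 sex. Loss of the Y chromosome, and female cells that had lost the inactive X, remain open as hypotheses, and the sex of the donors is not given in the sources used here.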

How the results depend on the processing

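Crossed replicate numbers and the run without chromosomes X and Y were chosen only after the result was seen. For the gene counts and the overlap, 120 values under alternatives stayed within 1.5 times the main count and 10 did not. Asking for at least 2-fold, a stricter criterion by construction, gave 1848 genes for null against wild-type BM-MSC, 2057 for ASC, 2232 for the difference, 4287 between null and 4054 between wild-type cultures, 6526 and 6362 for the tumor line against null and wild-type BM-MSC, and 471 genes called alike in BM-MSC and ASC. Median centring gave 4735 for the difference and 2617 called alike. With it the larger side turned from lower to higher for the difference (2647 higher, 2088 lower) and between null cultures (6228 and 4737). The same held for the tumor line against null (8146 and 6564) and wild-type BM-MSC (7965 and 6231). It also held between wild-type cultures (5183 and 5003) and for null against wild-type BM-MSC (3121 and 3115). The series matrix turned null against wild-type ASC (5024 and 4867) and the wild-type cultures (6255 and 6110). It also turned the tumor line against null (8076 and 7674) and wild-type BM-MSC (7805 and 7576). Quantile normalization (7863 and 7825) and normexp (8083 and 7964) turned the tumor line against null BM-MSC. The cause was not tested. Median centring moved the median change of all genes by 0.102 between null cultures and by 0.103 and 0.126 for the tumor line against null and wild-type BM-MSC. No scaling moved the share of calls that were higher by over 10 points. Leaving out 1 array, with its lone partner assumed to vary like the others, gave 6448 to 6842, 7444 to 8140, 5395 to 6514, 10610 to 11141, 10361 to 11100, 14035 to 14597 and 13695 to 14195 genes in the same order, fewer arrays being left. With replicate numbers as a block the counts were 8507, 8974, 6707, 12284, 11933, 15549 and 15095, although the numbers do not pair cultures (correlations of deviations -0.122 to 0.116). Crossed numbers gave 8945 genes between wild-type cultures.

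Of 740 named gene results past the threshold, 633 were past it in every setting that gave a value, the 2-fold threshold included. The setting with only genes above background on all 10 arrays gave a value for 428 named gene results. The run without chromosomes X and Y gave one for 713. Ncam1 in null against wild-type ASC turned to 0.0371 with the mean of its probes, which disagree. Saa3 in the difference of effects turned to 0.76 with normexp, whose offset compresses dim signals. Of the list results 2967 kept their side of the threshold with no turn counted. Another 95 lost the call (55 of them with an estimated correlation), 128 gained one and 7 turned direction. A turn was counted only where the list was called in the main run or in the alternative. With fry the turned lists had adjusted p = 0.00165 (CDK inhibitors, ASC), 0.0219 (macrophage, null cultures), 0.000525 (imprinted, wild-type cultures), 0.000192 and 0.00246 (neural, tumor line against null and wild-type BM-MSC) and 0.000321 (epithelial-mesenchymal, tumor line against wild-type BM-MSC), fry not comparing a list with other genes. The Hox list between wild-type cultures turned at adjusted p = 0.943 with genes above background on all 10 arrays, which leaves out Hox genes silent in 1 tissue. Signal over background limits what can be said of genes at background in 1 group, for which a comparison of 2 groups gives only a bound.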

Other observations

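Levels of single blood cell markers, and the genes picked out of the imprinted, surface and epithelial lists here, were chosen only after their values were seen, and no further test was run. Imprinted growth genes moved far apart in the tumor line. Mest, a maternally imprinted gene, was at least 959-fold lower than in null BM-MSC on all 3 probes, and the growth-restraining RNA H19 fell by 7.43, while Meg3, the noncoding partner of Dlk1 in an imprinted cluster, rose by 4.36 ± 0.17 with Dlk1. The list was not called as a set, its members going both ways, with 4 higher and 9 lower of 13 (4 and 9 adjusted over the list alone) and adjusted p = 0.170. Among surface markers of mesenchymal cells, endoglin (Eng, -5.25 ± 0.07) and the niche chemokine Cxcl12 (-4.46 ± 0.08) fell and Cd34 (4.76 ± 0.09) and Alcam (4.48 ± 0.11) rose, with 10 higher and 6 lower of 19 (10 and 6 adjusted over the list alone) in all and adjusted p = 0.432.

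Markers of blood cells in the tumor line ranged widely. Cd14 averaged 1.93 ± 0.08 and Cd68 0.60 ± 0.10, above null BM-MSC (0.48 ± 0.07 and -0.87 ± 0.07), and Itgam, at 4.23 ± 0.07 in null BM-MSC, changed by -1.43 ± 0.12. Tyrobp averaged -1.93 ± 0.02, C1qa -2.53 ± 0.10 and Hba-a1 -0.12 ± 0.07, each well above its level in null BM-MSC (-6.71 ± 0.53, -7.49 ± 0.26 and -4.10 ± 0.28), while the leukocyte surface protein Ptprc averaged -5.59 ± 0.14 in the tumor line and -5.06 ± 0.12 in null BM-MSC. Skeletal muscle markers, measured because sarcomas can carry them, gave 0 higher and 3 lower of 5 (0 and 3 adjusted over the list alone), with the skeletal actin Acta1 at least 117-fold lower and adjusted p = 0.170 for the list. In null BM-MSC against wild-type BM-MSC Cdh1 was at least 8.31-fold higher beside the keratin Krt18, with 5 higher and 2 lower of 13 (6 and 2 adjusted over the list alone) epithelial-mesenchymal regulators and adjusted p = 0.156.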
